A study of Homo sapiens with 6 samples.

How the data were processed

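RNA-seq was made from 293A cells, a human embryonic kidney line, after 24 hours with the small molecule PY-60 or with its solvent DMSO, in 3 libraries per group. The labels call the libraries biological replicates, number them 1 to 3 in each group, and give about 58000000 paired-end reads per sample. Each column of the table was assigned to a group by the treatment its name shares with the sample titles.

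The authors deposited 1 table of TPM, a transcript abundance scaled to a fixed total per library, per gene symbol, made with kallisto on GRCh37.p13, per the submitters' processing notes. The version of kallisto, the annotation and the way transcripts were summed to genes are not given in the sources used here. The table held 21695 rows, and its listed rows summed to between 662107 and 665700 TPM per library, so the rows analysed here are part of each library's total. TPM keeps no record of depth, so the number of reads behind a value is unknown, and no counting interval or detection floor is given. A value of 0 may be a failed estimate, and a gene with zeros is described as listed at 0. No coordinates are printed, because the annotation at hand is of another build than that of the authors. Of the 21695 symbols, 20917 were current symbols in a table of human gene names, and older symbols were matched through the same table. A RefSeq table of GRCh38 served only to tell protein-coding genes from pseudogenes.

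From the deposited TPM, log2(TPM + 1) was computed and genes with a mean of at least 1 TPM over the 6 libraries were kept, which left 10588 genes, 9960 of them protein-coding and 576 pseudogenes. PY-60 was compared with DMSO by limma 3.58.1 in R 4.3.3, a moderated 2-sided test with an empirical Bayes mean trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All log2 fold changes are PY-60 minus DMSO on the log2(TPM + 1) scale, which understates the change of genes of low abundance. Folds are ratios of mean TPM. No replicate number entered the model, since the labels do not say that a number marks a shared culture or day. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so the p-values rest on the spread pooled across genes.

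The design, the alternatives and 38 gene lists were fixed before the data were examined. The lists covered YAP/TAZ targets and Hippo components, annexins, the cell cycle, stress and signalling pathways, metabolism, ribosomes, histones and markers of cell types. Lists with at least 5 measured genes (34 of the 38) were tested with camera of the limma package at a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, served as alternatives. With an estimated correlation, camera rests on the few residual degrees of freedom of this design. A call lost there therefore does not by itself show that the genes of a list are correlated. Genes named in the text were the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 TPM in the higher group and no overlap between the groups, leaving out unnamed loci and pseudogenes. They were joined by 13 genes set beforehand (ANKRD1, CYR61, CTGF, AMOTL2, LATS2, YAP1, WWTR1, TEAD1 to TEAD4, ANXA2 and S100A10) and by up to 4 members with the smallest adjusted p of each list described. YAP1, TEAD3 and S100A10 were not analysed here, and some genes that the rule names are not reported here. Other genes named were chosen after their values were seen, as said beside them.

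On simulated data with the real means and spreads of the 10588 genes, limma recovered 98 of 100 genes changed by 1 on the log2 scale and 27 of 100 changed by 0.25, with 4 false calls among 129. Far fewer genes changed there than were called in the data, which makes the adjusted threshold stricter, so these rates need not hold for the data. Camera called 10 of 10 simulated lists shifted by 0.5 and 0 of 30 that were not shifted, with genes that varied independently.

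Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-ratio rescaling, quantile normalization, limma without the trend and with robust estimation, the replicate number as a block, a threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Chosen after seeing the data were a test on protein-coding genes alone and the comparison of each list with 10000 random lists of the same size matched on mean expression in 20 classes. Further lists, for tissue lineages, abundant neuronal transcripts, genes repressed by REST and genes known to respond to histone deacetylase inhibitors, were chosen once the main results were known and serve only the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.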

Results

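Gene expression was measured by RNA-seq in 293A cells, a line derived from human embryonic kidney cells, treated for 24 hours with PY-60 or with the solvent DMSO. Each group held 3 libraries, labelled as biological replicates. The study's title presents PY-60 as a small molecule that acts on annexin A2 and activates YAP, the transcriptional co-activator at the end of the Hippo pathway. The comparison therefore asks which transcripts differ between PY-60 and DMSO, and among them the targets of YAP and its relative TAZ. Values are TPM, and the number of reads behind each value is unknown. Between 10021 and 10046 genes reached 1 TPM in the DMSO libraries and between 10842 and 10968 in the PY-60 libraries. On log2(TPM + 1) across the 10588 genes tested, Pearson correlations, which are across genes and not across independent replicates, lay between 0.9958 and 0.9971 within groups and between 0.9497 and 0.9547 between groups.

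Canonical YAP/TAZ target genes were among the transcripts that rose with PY-60. ANKRD1, which encodes a cardiac ankyrin repeat protein, rose from 77.4 ± 6.67 TPM in DMSO to 530 ± 26.4 TPM (SD, n = 3 per group), a 6.85-fold difference with a log2 fold change of 2.76 (SE 0.06, limma adjusted p = 9.4e-10). The matricellular genes CTGF (now CCN2) and CYR61 (now CCN1) rose 5.56-fold and 4.59-fold, CTGF from 45.5 ± 2.27 to 253 ± 13.5 TPM and CYR61 from 55.3 ± 2.87 to 254 ± 14.4 TPM. IGFBP3, which encodes an insulin-like growth factor binding protein, rose from 2.54 ± 0.42 to 27.6 ± 0.94 TPM (log2 fold change 3.02). AMOTL2, an angiomotin family gene, rose less, from 28.5 ± 0.68 to 40.8 ± 1.39 TPM.

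Of the 17 measured core YAP/TAZ targets, 12 rose, 2 fell (FJX1 and ARHGEF17, both named after their values were seen) and 3 did not pass the threshold, and the counts adjusted over the list alone were also 12 and 2. The median log2 fold change of the list was 0.50 (0.19 after quantile normalization), and camera placed it above the other genes (adjusted p = 0.022). With an estimated inter-gene correlation this call was lost (adjusted p = 0.54 with an estimated correlation). In a wider list of 43 measured YAP/TAZ targets, 25 rose and 9 fell, with a median of 0.26, and the list did not pass the threshold (camera adjusted p = 0.19), although its median lay at percentile 99.98 of random lists matched on mean expression. Among its leading members, LMCD1 rose from 28.9 ± 0.64 to 72.7 ± 2.39 TPM and the transglutaminase gene TGM2 from 7.77 ± 0.81 to 38.6 ± 1.15 TPM, and SLIT2 fell.

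**Figure D1:**
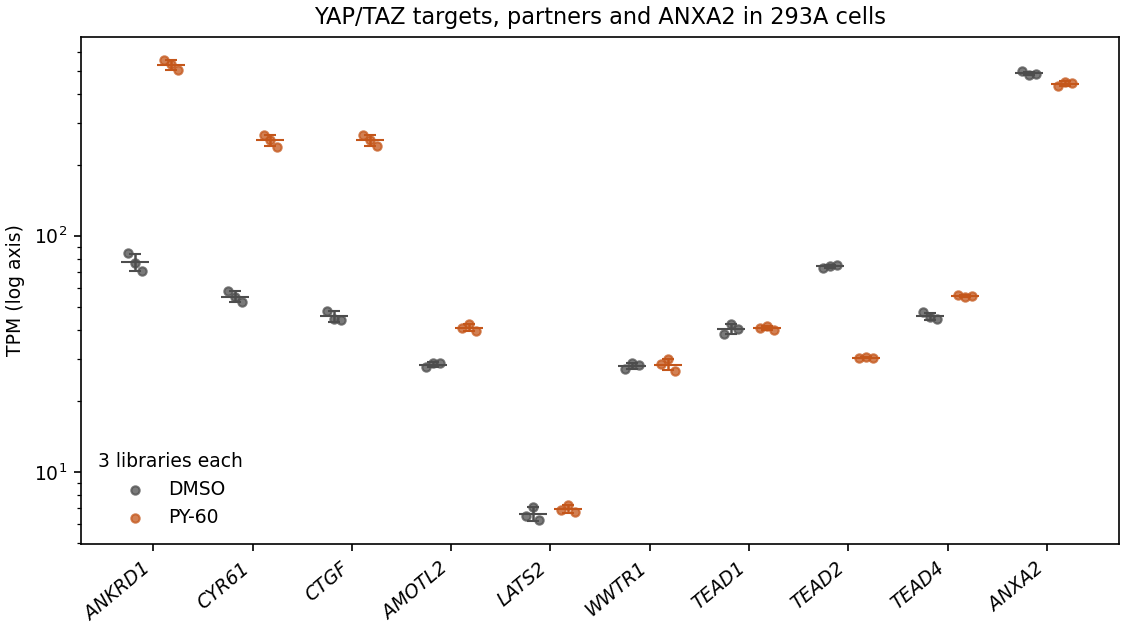
TPM on a log axis of 10 genes set before the data were examined, in the 3 DMSO libraries (grey) and the 3 PY-60 libraries (orange) of 293A cells. Points are single libraries, horizontal bars are means and error bars are SD. ANKRD1 lies at 77.4 TPM in DMSO and 530 TPM with PY-60, and TEAD2 at 74.2 and 30.5 TPM.

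Among the partners and regulators of YAP, the DNA-binding factor gene TEAD2 fell from 74.2 ± 1.06 to 30.5 ± 0.18 TPM (log2 fold change −1.26, adjusted p = 4.0e-09), while TEAD4 rose from 45.7 ± 1.61 to 55.7 ± 0.58 TPM (0.28). TEAD1 was at 40.2 ± 2.01 and 40.7 ± 0.90 TPM and WWTR1, the gene of TAZ, at 28.1 ± 0.73 and 28.4 ± 1.58 TPM, neither past the threshold. LATS2, the gene of a YAP kinase and itself a core target, was at 6.63 ± 0.45 and 6.96 ± 0.27 TPM (adjusted p = 0.46), and quantile normalization placed it lower with PY-60. YAP1 and TEAD3 were not analysed here. Of the 26 measured Hippo pathway components, 8 rose and 5 fell (median 0.06, camera adjusted p = 0.76). FGFR1OP2 and WWC1 rose, FGFR1OP2 from 53.5 ± 2.44 to 82.5 ± 2.59 TPM.

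ANXA2, the gene of the protein named in the title, was among the abundant transcripts of both groups and fell from 487 ± 8.61 to 441 ± 9.49 TPM (log2 fold change −0.15, adjusted p = 0.0015), a direction that turned with quantile normalization (0.04). Of the 8 measured genes of the annexin and S100 list, 5 rose and 2 fell (median 0.29, camera adjusted p = 0.55). ANXA1 rose from 291 ± 5.99 to 389 ± 16.2 TPM, ANXA3 from 17.9 ± 1.01 to 24.2 ± 0.73 TPM and ANXA8 from 1.78 ± 0.098 to 4.41 ± 0.24 TPM, the last uncertain because it has near-identical copies. ANXA11 fell from 166 ± 4.91 to 129 ± 4.11 TPM. S100A10 was not analysed here.

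Across all genes tested, limma called 7110 of 10588 (67.2%), of which 4006 were higher and 3104 lower with PY-60. Large changes lay mostly on 1 side, with 1034 genes at least 2-fold higher and 34 at least 2-fold lower by a log2 fold change of 1 or more. The genes at least 2-fold higher were scarce in DMSO, with a median of 1.56 TPM there and 7.43 TPM with PY-60, and 405 of them (39.2%) averaged under 1 TPM in DMSO. The median log2 fold change was 0.48 for genes with a mean of 2 to 4 TPM and −0.12 for genes of 64 to 256 TPM. In 7449 genes (70.4%) the 3 values of 1 group lay above all 3 of the other, where chance gives 10%. The share of higher genes among the calls, 56.3%, was 41.9% after quantile normalization, which moved the median of all genes by −0.10. With no filter on low values the share was 64.6%, and with the filter at 5 TPM it was 49.0%.

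**Figure D2:**
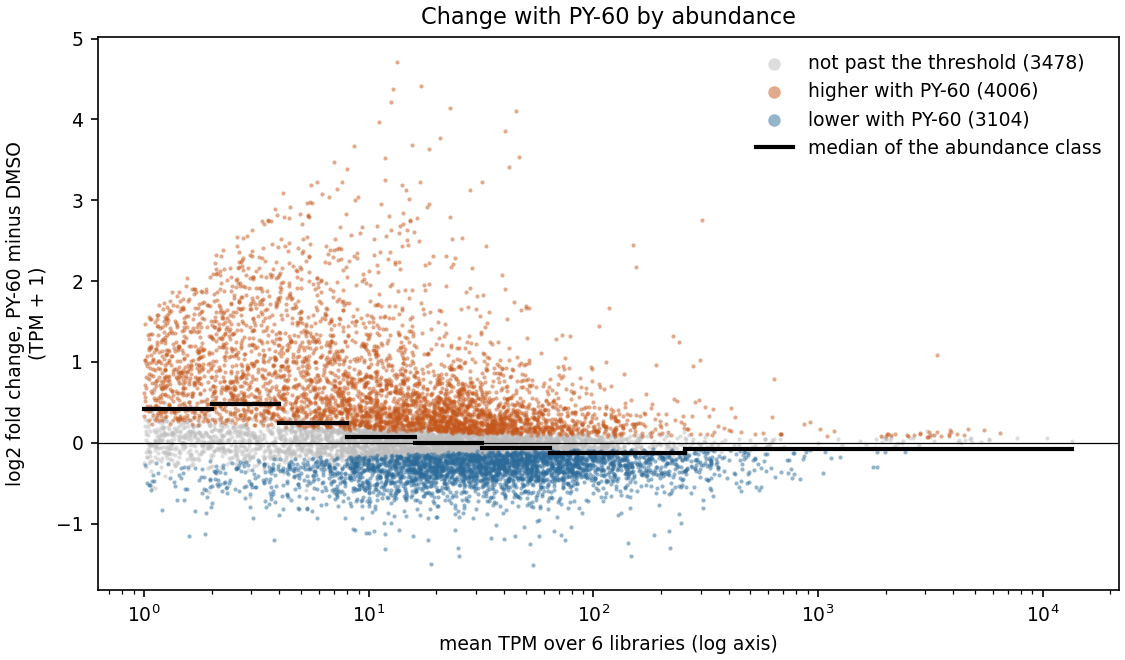
Log2 fold change of each of the 10588 genes tested, PY-60 minus DMSO on log2(TPM + 1), against its mean TPM over the 6 libraries on a log axis. Orange and blue points are the 4006 genes called higher and the 3104 called lower, grey points the rest, and black lines medians of abundance classes, which fall from 0.42 at 1 to 2 TPM to −0.12 at 64 to 256 TPM.

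Of the 10 genes with the highest log2 fold changes, 5 averaged under 1 TPM in DMSO and the others under 5 TPM. CACNG7, an auxiliary calcium channel subunit, rose from 0.62 ± 0.085 to 33.5 ± 1.44 TPM (log2 fold change 4.42, SE 0.07), HLA-DRA, an MHC class II chain, from 0.25 ± 0.036 to 25.4 ± 5.79 TPM, and CCK, the gene of the peptide hormone cholecystokinin, from 0.39 ± 0.090 to 24.7 ± 1.21 TPM. BEX1 rose from 1.58 ± 0.024 to 44.5 ± 1.88 TPM, CGA, the common alpha chain of glycoprotein hormones, from 4.15 ± 0.99 to 86.1 ± 2.92 TPM, and the calcium-binding protein gene PVALB from 0.44 ± 0.039 to 21.6 ± 2.12 TPM. OLFM1, SUSD4 and KRTAP19-5 rose by 3.86, 3.77 and 3.69 on the log2 scale. The histone gene HIST2H2AA3 (4.71) was listed at 0.14, 0 and 0 TPM in DMSO and at 22.4, 31.8 and 25.7 TPM with PY-60, and is uncertain because it has a near-identical copy.

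The genes with the lowest log2 fold changes were abundant or moderately expressed in DMSO. UROD, an enzyme of heme synthesis, fell from 80.2 ± 0.38 to 27.5 ± 2.08 TPM (log2 fold change −1.51, SE 0.05), the guidance ligand gene SLIT2 from 213 ± 11.5 to 80.3 ± 4.78 TPM, and the transcription factor genes FOXC1 from 36.8 ± 1.09 to 13.4 ± 0.56 TPM and HOXA3 from 17.2 ± 1.13 to 6.33 ± 0.24 TPM. The RNA-binding protein gene HNRNPM fell from 201 ± 12.7 to 84.4 ± 10.0 TPM. TEAD2, given above, TNRC18 (−1.31), SPEN (−1.21) and WASHC2C (−1.20) were also among the 10 lowest, and WASHC2C is uncertain because it has a near-identical paralog.

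Genes of DNA replication fell together. Of 25 measured G1/S and replication genes, 20 fell and 1 rose, MYC (named after its values were seen), with a median of −0.30 (camera adjusted p = 2.0e-05, adjusted p = 0.50 with an estimated correlation). The thymidylate synthase gene TYMS fell from 312 ± 4.85 to 170 ± 4.77 TPM, the helicase subunit gene MCM7 from 275 ± 3.63 to 188 ± 0.20 TPM, PCNA, the sliding clamp, from 414 ± 13.8 to 313 ± 6.65 TPM, and the licensing factor gene CDT1 from 250 ± 5.75 to 164 ± 13.9 TPM. Of 24 G2/M and mitosis genes, 13 fell and 4 rose, with a median of −0.16 (camera adjusted p = 0.0062, adjusted p = 0.54 with an estimated correlation). UBE2C fell from 214 ± 4.23 to 163 ± 1.26 TPM and the mitotic kinase gene PLK1 from 98.8 ± 5.14 to 70.0 ± 2.77 TPM.

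Of 16 measured p53 target genes, 11 fell and 1 rose, with a median of −0.26 (camera adjusted p = 0.0025, adjusted p = 0.50 with an estimated correlation). The pro-apoptotic gene BAX fell from 326 ± 9.22 to 164 ± 8.26 TPM, CCNG1 from 380 ± 17.1 to 232 ± 12.6 TPM and BBC3 from 55.6 ± 0.68 to 40.6 ± 2.41 TPM.

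Neuronal markers and histone genes showed the highest list medians. All 11 measured neuronal markers rose (3 others in the table averaged under 1 TPM), with a median of 1.54 (camera adjusted p = 8.4e-05, adjusted p = 0.42 with an estimated correlation). GAP43, a growth cone protein gene, rose from 5.79 ± 0.35 to 32.8 ± 1.37 TPM, the neuronal tubulin gene TUBB3 from 24.2 ± 1.02 to 79.3 ± 3.38 TPM, the synaptic gene SNAP25 from 1.38 ± 0.15 to 7.56 ± 0.32 TPM and the neurofilament gene NEFM from 2.69 ± 0.39 to 12.7 ± 0.44 TPM. Of 12 measured replication-dependent histone genes (14 were in the table), 10 rose and 0 fell, with a median of 0.94 (camera adjusted p = 0.0023, adjusted p = 0.50 with an estimated correlation). With no filter on low values the median was 0.79. Whether the rise of these genes relates to DNA replication was not tested. HIST1H2BD rose from 11.04 ± 0.76 to 32.5 ± 1.65 TPM and HIST1H2AC from 4.38 ± 0.21 to 10.8 ± 0.75 TPM, and members of this family are near-identical.

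Most measured genes of the extracellular matrix list and of the TGF-beta/SMAD target list also rose, although several alternatives ended the call of the latter list. Of 21 measured matrix and adhesion genes, 14 rose and 2 fell, with a median of 0.59 (camera adjusted p = 0.022, adjusted p = 0.58 with an estimated correlation). The thrombospondin gene THBS2 rose from 2.36 ± 0.17 to 15.5 ± 1.05 TPM, POSTN (periostin) from 0.43 ± 0.10 to 6.08 ± 0.44 TPM and the gelatinase gene MMP2 from 29.1 ± 0.41 to 61.9 ± 2.38 TPM. Of 18 TGF-beta/SMAD targets, 12 rose and 2 fell, with a median of 0.27 (camera adjusted p = 0.039, adjusted p = 0.50 with an estimated correlation). The inhibitors of differentiation ID1 and ID3 rose from 190 ± 7.04 to 368 ± 21.6 TPM and from 265 ± 5.26 to 361 ± 12.002 TPM.

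Changes of the translation, respiration and chaperone lists were small. Of 48 cytosolic ribosomal protein genes, 25 rose and 0 fell, with a median of 0.08 (camera adjusted p = 0.035, adjusted p = 0.66 with an estimated correlation) that was 0.00 after quantile normalization. RPS24 rose from 5148 ± 139 to 5769 ± 27.3 TPM. Of 20 ribosome biogenesis genes 9 fell and 1 rose, with 6 and 1 adjusted over the list alone (median −0.13, camera adjusted p = 0.039, adjusted p = 0.54 with an estimated correlation), and PES1 fell from 97.2 ± 2.77 to 68.5 ± 2.21 TPM. Of 25 nuclear oxidative phosphorylation genes 13 fell and 5 rose (median −0.11, camera adjusted p = 0.028, adjusted p = 0.54 with an estimated correlation), a median that was 0.031 after quantile normalization, and NDUFB10 fell from 661 ± 18.3 to 454 ± 27.9 TPM. Of 14 heat shock genes 9 fell and 2 rose (median −0.21, camera adjusted p = 0.039, adjusted p = 0.54 with an estimated correlation). SERPINH1, a collagen chaperone gene, fell from 188 ± 3.50 to 124 ± 3.06 TPM, and CHORDC1 and HSPA4L rose.

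**Figure D3:**
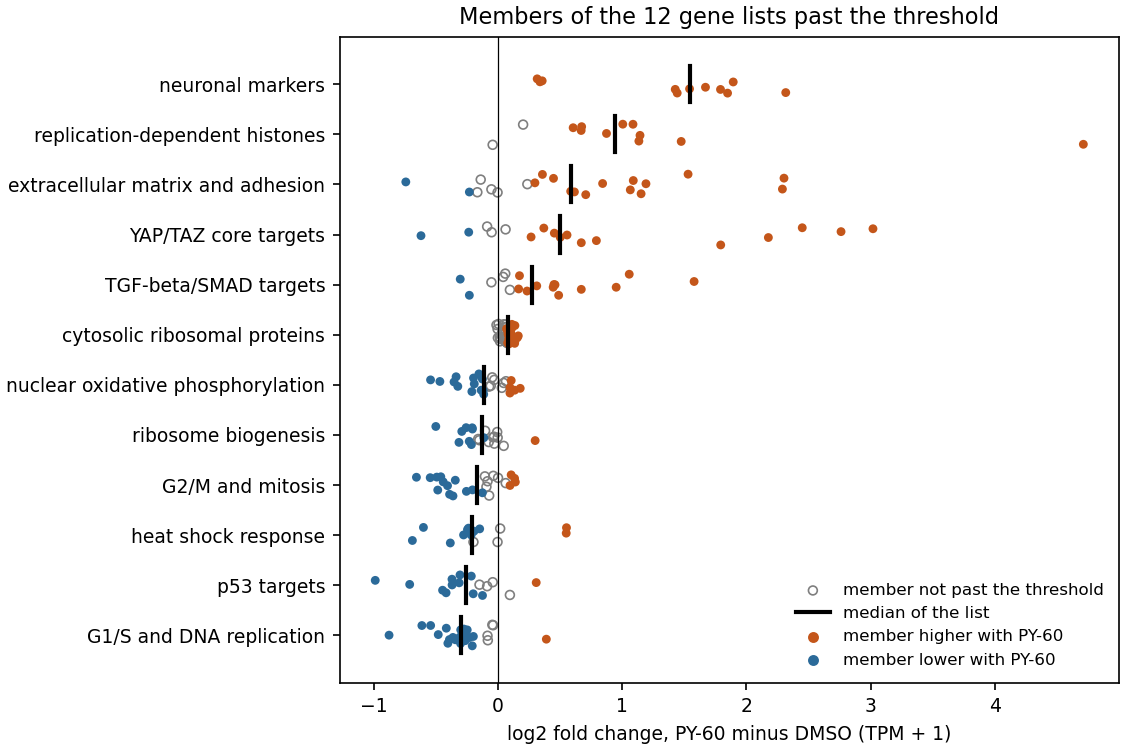
Log2 fold change, PY-60 minus DMSO on log2(TPM + 1), of each measured member of the 12 gene lists that passed the threshold of camera with the preset correlation. Filled points are members called higher (orange) or lower (blue), open circles members that were not called, and black bars list medians, from 1.54 for neuronal markers to −0.30 for G1/S and replication genes.

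The other stress and signalling lists held members that moved both ways and did not pass the threshold as lists. Of 13 unfolded protein response genes 9 rose and 1 fell (median 0.36, camera adjusted p = 0.0504, and past the threshold with quantile normalization, 0.012, and several other settings), and HERPUD1 rose from 47.6 ± 2.51 to 91.7 ± 6.62 TPM. Of 24 integrated stress response genes 12 rose and 5 fell (adjusted p = 0.23), and the asparagine synthetase gene ASNS rose from 68.1 ± 1.42 to 129 ± 6.51 TPM. Of 16 NRF2 targets 9 rose and 6 fell (adjusted p = 0.35), and AKR1C3 rose from 5.62 ± 0.92 to 23.5 ± 1.86 TPM. Of 12 immediate early genes 10 rose and 1 fell (adjusted p = 0.087), and DUSP1 rose from 142 ± 6.75 to 339 ± 26.9 TPM. Of 14 SRF/MRTF and actin genes 8 fell and 3 rose (adjusted p = 0.10), and TAGLN2 fell from 652 ± 13.4 to 436 ± 10.1 TPM. Interferon response genes (14 of 23 rose, 2 fell, adjusted p = 0.10), NF-kB and inflammatory genes (9 of 14 rose, 4 fell, adjusted p = 0.29) and hypoxia targets (8 of 16 rose, 4 fell, adjusted p = 0.53) held IFI6, from 36.4 ± 1.43 to 80.0 ± 2.15 TPM, BIRC3, from 2.51 ± 0.19 to 8.59 ± 0.63 TPM, and LOX, from 6.31 ± 0.18 to 15.3 ± 0.68 TPM. Of 9 AHR targets 2 rose and 4 fell (adjusted p = 0.93), and this list had a positive median (0.046) and mean (0.29) while camera gave a downward direction.

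Single markers of other cell types rose as well, most from low levels, while none of these lists passed the threshold. A marker close to silent in DMSO counts as measured only if it rose. Of 9 endothelial markers in the table, 4 were measured, too few for a list test, and were called higher, among them KDR, a VEGF receptor gene, from 0.38 ± 0.076 to 8.45 ± 0.67 TPM and VWF from 1.18 ± 0.11 to 4.30 ± 0.51 TPM. Of 7 renal markers 5 rose and 1 fell (median 0.54, camera adjusted p = 0.19), and LRP2, the gene of megalin, rose from 1.86 ± 0.15 to 12.7 ± 1.02 TPM. Of 8 epithelial markers 4 rose and 3 fell (adjusted p = 0.62), and CDH1 rose from 1.78 ± 0.14 to 6.19 ± 0.24 TPM. Of 10 mesenchymal markers 5 rose and 2 fell, with 5 and 3 adjusted over the list alone (adjusted p = 0.53). CDH11 rose from 0.40 ± 0.22 to 5.13 ± 0.87 TPM and VIM fell from 884 ± 7.58 to 653 ± 25.2 TPM. Of 5 immune markers 3 rose and 1 fell (adjusted p = 0.42), with CD74 up from 0.98 ± 0.10 to 5.50 ± 0.46 TPM and CD68 down from 11.8 ± 0.50 to 5.14 ± 0.79 TPM.

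Of the 34 lists tested, camera with the preset correlation called 12, 6 upward and 6 downward, and with an estimated correlation 0 (1 at an unadjusted p under 0.05), while fry called 31. The other 9 splits of the 6 libraries into groups of 3 gave between 3 and 11 list calls. Part of the difference between PY-60 and DMSO remains in each of those splits, so these calls are not a chance rate. Against random lists matched on mean expression, 8 of the 12 stood outside the central 95% of the random medians, and the G2/M, heat shock, ribosome biogenesis and oxidative phosphorylation lists did not. Of the lists that camera did not call, 5 also stood outside, the wider YAP/TAZ, cholesterol synthesis, integrated stress response, unfolded protein response and NRF2 lists. Calls of the YAP/TAZ core, G1/S, histone, matrix and neuronal lists held under each other alternative, while quantile normalization ended those of the G2/M (camera adjusted p = 0.29), p53 (0.052), heat shock (0.54), ribosomal protein (0.69), ribosome biogenesis (0.32) and oxidative phosphorylation (0.54) lists. Leaving out PY-60 replicate 1, PY-60 replicate 3 or DMSO replicate 2 ended those of the TGF-beta (0.050, 0.053 and 0.068), heat shock (0.057, 0.058 and 0.055), ribosome biogenesis (0.070, 0.053 and 0.055) and ribosomal protein (0.05002, 0.13 and 0.15) lists, DMSO replicate 1 those of the TGF-beta and heat shock lists (0.051 each), and DMSO replicate 3 that of the ribosome biogenesis list (0.051). Except for the ribosome biogenesis and mesenchymal lists, the counts adjusted over the list alone equalled those over all genes tested.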

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

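Of the tests in this part, the ratio of summed TPM, the splits of the libraries, the test of genes of other lineages and the comparison with matched random lists were chosen after the result was seen.

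The 11107 genes with a mean under 1 TPM, which the main comparison does not use, summed to 920 ± 27.6 TPM in the DMSO libraries and 1714 ± 99.2 TPM in the PY-60 libraries (SD, n = 3 per group), a ratio of 1.86. Each PY-60 library lay above each DMSO library, the most that an exact permutation test of 3 against 3 can show (p = 0.1). Of the 7887 of these genes above 0 in at least 1 library, 2013 (25.5%) had all 3 PY-60 values above all DMSO values and 174 (2.21%) all 3 below. Chance gives at most 5% each way, and less where values tie at 0, so the 2.21% is not read as a lack of falls.

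The same rise ran through the tested genes of low abundance: of 2060 with a mean of 1 to 5 TPM, 1201 were called higher and 181 lower. Genomic DNA carried into the PY-60 libraries would cover silent genes too, yet the 219 olfactory receptor genes had a median gain of 0 TPM (0% of the 1.98 TPM median gain of the 1201 genes), with an upper quartile of 0.0058 TPM. Deeper PY-60 libraries would detect more genes without raising their summed TPM, which the ratio of 1.86 argues against. Neuronal cells mixed into the PY-60 cultures stay open: of 17 genes of other lineages with at least 1 TPM in DMSO, 9 were called higher and 2 lower, a share between the bounds, which were set with these values known. The bounds first set against such mixing were met (5 of 10 lineage lists with most measured genes called higher, and a median gain of 7.44 TPM in 15 abundant neuronal transcripts against 33.1 TPM in 8 named neuronal genes). They are not used, because the filter on the mean lets near-silent genes in only if they rose and the named genes were picked for their rise. Also open is an effect of PY-60 on the cells, which was not tested apart from the group comparison itself.

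The rise of the core YAP/TAZ target list may in principle be part of this rise of scarce genes. Among 10000 random lists matched on mean expression, however, the list median of 0.50 lay at percentile 99.9, against a median of 0.04 for the random lists, which argues against abundance alone as its source. The matching does not model correlation among the targets, and with an estimated correlation the call was lost (camera adjusted p = 0.54). That loss cannot decide whether correlation explains the call, because the test with an estimated correlation has few degrees of freedom here. For the neuronal markers, whose estimated correlation of 0.022 was near the preset 0.01, the unadjusted camera p still moved from 5.0e-06 to 0.012.

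With 3 libraries against 3 there are 10 splits, too few for a share under 0.1. The real split called 7110 genes with limma and the highest of the other 9 called 0 (15 to 142 at an unadjusted p under 0.05), so 1 split gave as many. For the lists, the real split gave 12 camera calls at the preset correlation and the highest of the others 11. The other splits mix PY-60 and DMSO unequally, so each keeps part of the difference and has a wider spread within its groups. Neither the 0 nor the 11 therefore tells how often chance gives such counts.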

How the results depend on the processing

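The comparison of lists with random lists matched on mean expression and the test on protein-coding genes were chosen after seeing the data. Gene counts stayed within 1.5 times of 4006 higher and 3104 lower under every alternative except the requirement of an absolute log2 fold change of at least 1, which left 1034 higher and 34 lower by construction. Without each library, 3617 to 3976 genes were higher and 2724 to 3157 lower. Quantile normalization gave 3137 higher and 4342 lower. The median of the YAP/TAZ core list was 0.19 with quantile normalization and 0.37 with the filter at 5 TPM, both called. The list lost its call with an estimated inter-gene correlation (adjusted p = 0.54) and had its lowest adjusted p with fry (9.7e-05). Of the other 33 lists, 11 were called; with no filter on low values 17 were, with quantile normalization 7, with an estimated correlation 0, with fry 30, and without each library in turn 7 to 12 (7 without DMSO replicate 2, PY-60 replicate 1 or PY-60 replicate 3), and the cause was not tested. Median-ratio rescaling ended the calls of the TGF-beta (adjusted p = 0.056) and ribosomal protein (0.28) lists, a fit without the mean trend those of the heat shock (0.056), TGF-beta (0.056) and ribosomal protein (0.19) lists, and the filter at 5 TPM those of the heat shock (0.11), TGF-beta (0.074), ribosome biogenesis (0.14) and oxidative phosphorylation (0.095) lists. The unfolded protein response was called with quantile normalization (0.012), the filter at 5 TPM (0.023), no filter (0.024), the replicate block (0.045), a pseudocount of 0.1 (0.047) and without DMSO replicate 3 (0.040) or PY-60 replicate 2 (0.033). No filter also added the SRF/MRTF, immediate early, interferon, autophagy and renal lists, and quantile normalization the cholesterol list. The oxidative phosphorylation list turned from −0.11 to 0.031 with quantile normalization and to 0.004 relative to matched random lists, and fry placed the AHR targets (0.046) upward where camera placed them downward. Among called lists, medians moved over 1.5 times with quantile normalization for histones (0.50), heat shock (−0.098) and ribosomal proteins (0.00), with a pseudocount of 5 for histones (0.56) and neuronal markers (0.76), with the filter at 5 TPM for TGF-beta (0.17) and without DMSO replicate 3 for ribosome biogenesis (−0.087). Medians of most uncalled lists moved as much under at least 1 setting, the wider YAP/TAZ list to 0.11 with quantile normalization and 0.148 with the filter at 5 TPM, and the renal list to 0.179 with quantile normalization. Those of the AHR (−0.314), glycolysis (0.006) and immune (−0.047) lists changed sign with quantile normalization, and those of the AHR (−0.163), NF-kB (−0.105), epithelial (−0.079) and mesenchymal (−0.094) lists with the filter at 5 TPM. A pseudocount of 5 gave CACNG7 2.78 and HLA-DRA 2.52. Among 165 named or listed genes, quantile normalization turned ANXA2 (0.04), CD4 (−0.047) and PAX2 (−0.047), none of them called there, and LATS2 (−0.30), called lower, and the cause was not tested; 6 other genes lost and 1 gained a call there. Without PY-60 replicate 1, AHRR lost its call. The other alternatives run gene by gene changed none, with 142 of the genes left by the filter at 5 TPM; the requirement on the log2 fold change was applied to the counts alone. With the replicate number as a block, 4148 genes were higher, 3286 lower and 13 lists were called. Residuals of equally numbered libraries correlated at 0.048, 0.23 and 0.14, and 5 of 6 libraries correlated best with their own number. Pairing by number therefore stays open. Depth is unknown. In simulation 27 of 100 changes of 0.25 were recovered, but far fewer genes changed there than were called in the data, so recovery in the data may differ.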

Other observations

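The tests of REST and of histone deacetylases and all values for the lineage lists were chosen after the results were seen. The bounds for REST and histone deacetylases were also set then. Metabolic lists fixed beforehand held large changes of single genes without passing the threshold as lists in the main comparison. Of 18 cholesterol synthesis genes 11 rose and 3 fell (median 0.21, camera adjusted p = 0.20, but 0.022 after quantile normalization, and percentile 99.95 of matched random lists), with DHCR7 up from 79.3 ± 3.71 to 132 ± 3.01 TPM and FDPS down from 141 ± 0.75 to 107 ± 2.76 TPM. Of 9 fatty acid synthesis genes 2 rose and 4 fell (adjusted p = 0.29), and ELOVL1 fell from 69.8 ± 1.43 to 47.5 ± 2.41 TPM. Of 17 glycolysis genes 6 rose and 9 fell (adjusted p = 0.19), with a median of −0.11 and a mean of 0.035. SLC16A3, a lactate transporter gene, rose from 9.71 ± 0.089 to 32.3 ± 2.505 TPM and LDHA fell from 574 ± 7.76 to 410 ± 15.3 TPM. Of 20 autophagy and lysosome genes 6 rose and 10 fell (adjusted p = 0.099), and LAMP1 fell from 63.2 ± 2.00 to 43.9 ± 0.24 TPM. Metallothionein and LXR target lists had 4 measured genes each, too few for a list test. The metal-binding genes MT1X and MT1F rose from 197 ± 5.07 to 400 ± 15.0 TPM and from 5.56 ± 0.65 to 16.5 ± 0.92 TPM, the LXR targets ABCG1 and APOE rose from 7.77 ± 0.32 to 17.1 ± 0.31 TPM and from 16.6 ± 1.26 to 30.5 ± 0.58 TPM, and NR1H3 fell. Mitochondrially encoded genes were not analysed here.

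Of 12 WNT targets 7 rose and 3 fell (adjusted p = 0.34), with DKK1, a secreted WNT inhibitor gene, up from 5.69 ± 0.20 to 29.8 ± 2.41 TPM and LEF1 down from 34.5 ± 0.64 to 21.5 ± 1.47 TPM. Of 7 NOTCH targets 4 rose and 3 fell (adjusted p = 0.67), and LFNG rose from 3.26 ± 0.12 to 11.5 ± 0.82 TPM. MHC class II genes were looked up after HLA-DRA was seen: of the 9 others measured, 8 rose and 0 fell, in a family picked because 1 member rose. HLA-DRB1 went from 25.1 ± 1.18 to 52.0 ± 1.65 TPM and HLA-DMA, at 4.44 ± 0.63 and 4.97 ± 0.16 TPM, did not pass the threshold. Lists of 10 lineages held 110 genes of the table, 17 of them at 1 TPM or more in DMSO, and 92 had a higher mean with PY-60. The called members included the myoglobin gene MB, from 0.32 ± 0.040 to 4.89 ± 0.42 TPM, and TNNI3 of cardiac muscle, from 4.86 ± 0.70 to 16.1 ± 1.48 TPM. Of the measured genes, which include near-silent ones only if they rose, those called higher were 5 of 5 for skeletal muscle, 4 of 6 for cardiac muscle, 2 of 3 for pituitary, 1 of 1 for erythroid cells and pancreas each, 1 of 2 for liver, retina and keratinocyte each and 0 of 2 for intestine, and no testis gene had a mean of 1 TPM. The keratinocyte gene DSC3 fell from 24.1 ± 1.77 to 13.3 ± 1.57 TPM, and 1 cardiac gene fell.

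A candidate explanation for the rise of neuronal genes is release from REST, the repressor of neuronal genes outside the nervous system. All 19 measured REST-repressed genes rose, with a median of 1.43, at percentile 99.99 among random lists matched on mean expression. The 12 measured neuronal genes that are not on that list also rose, with a median of 0.80 at percentile 100, a comparison added after the percentile was seen. These 12 genes were not checked for REST binding and may include further targets. The test therefore does not set REST apart from a rise of neuronal genes in general. REST itself was at 15.1 ± 0.16 TPM in DMSO and 13.3 ± 1.49 TPM with PY-60 (limma adjusted p = 0.055).

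A rise of scarce genes together with a fall of replication genes could also come from inhibition of histone deacetylases. Of 11 measured genes known to respond to such inhibitors, 8 (72.7%) were called in the known direction, between the bounds set for and against it, and 2 were called the opposite way. The 7 measured genes expected to rise, 5 called higher and 1 lower, had a median of 0.61, at percentile 99.99 among random lists matched on mean expression. Falls were common among abundant genes in general: of all tested genes at 64 to 256 TPM, 53.4% were called lower and 19.8% higher. The 11 are not all independent of the pattern, since TYMS, among the 8, and MYC, among the 2, also belong to the G1/S and replication list. DHRS2 rose from 55.4 ± 3.41 to 178 ± 5.54 TPM, CLU from 464 ± 11.99 to 805 ± 24.7 TPM and the linker histone gene H1F0 from 349 ± 12.04 to 470 ± 13.4 TPM, while CDKN1A, expected to rise, fell from 340 ± 5.54 to 296 ± 5.65 TPM and MYC, expected to fall, rose from 19.0 ± 1.78 to 25.2 ± 1.38 TPM. These values do not decide for or against this hypothesis.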
